A study of Saccharomyces cerevisiae EC1118 with 12 samples.

How the data were processed

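The 12 RNA samples came from chemostat cultures of the wine yeast Saccharomyces cerevisiae EC1118. RNA was labelled with biotin and hybridised to Affymetrix expression arrays, per the labels' protocols. The cultures were sparged with nitrogen or with gas holding 1%, 5% or 20% oxygen, 3 arrays in each of 4 groups. The deposited table holds log2 values for 5716 probe sets. The RMA method, which corrects background, normalizes arrays together and summarises the probes of a set, is named in the submitters' processing notes. Its version and settings are not given in the sources used here. That the deposited values are log2 was read from their range, and the distributions of the 12 arrays over these probe sets were not identical. RMA compresses differences of weakly hybridising probe sets, so small levels carry less information than high ones, and the number of arrays limits the precision.

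Of the probe sets, 5498 had 1 gene in the platform annotation and 218 had no gene name there. All 5498 identifiers matched the reference gene table, and 12 symbols were updated through it. Where a gene had several probe sets, which was so for 47 genes, the one with the highest mean over all arrays was taken. This left 5449 genes to test. No gene had probe sets that were called in opposite directions. The lowest 25% of genes by mean level, 1362 genes under 5.84, were marked as dim. PAU genes are near-identical copies and are reported as a family.

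The labels give the dissolved oxygen of the groups in conflicting ways. The titles imply 0, 1.2, 2.7 and 5 micromolar, and the condition text gives 0, 0.8, 4 and 11 micromolar. Groups are therefore named by the oxygen in the sparging gas. The series design also names 21 micromolar, which was not analysed here. The labels do not say whether the 3 arrays of a group came from separate chemostats, so p-values measure only the spread between these arrays, which may be technical.

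One model with a mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 4.11 prior degrees of freedom). Each oxygen level was compared with the anaerobic group, successive levels were compared with each other, and a moderated F test asked for any difference between the 4 levels. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Differences are given as log2 ± the standard error of the fit, and levels as mean ± SD of 3 arrays. A difference of 1 on this scale is a 2-fold change.

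A total of 31 gene lists, fixed with the design before the data were examined, were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Some genes stand in more than 1 list. Members are counted by their call over all genes and adjusted over the list alone. Camera compares a list with the other genes, and fry asks whether its members move one way. Named genes follow a rule set at the same time. It takes the 10 largest rises and 10 largest falls of each comparison with the anaerobic group, and 6 of each for the successive steps. These had to be called, with no overlap between the arrays of the groups, a gene symbol, no PAU name and a level that was not dim in the higher group. Chance alone gives no overlap for 10% of genes. The rule adds a fixed set of oxygen-related genes, and from each list up to 2 rises and 2 falls, or else the member with the smallest p.

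The fit and the list test were tested on simulated data with the real means and spreads. For 20% oxygen against anaerobic, with 200 of 5449 genes changed, 49% of the 100 genes changed by 1 on the log2 scale and 96% of the 100 changed by 2 were called, all with the right sign, beside 7 false calls. The simulated genes were independent of each other, which real genes are not. Alternatives were quantile and median scaling, leaving out dim genes, the mean of probe sets, all probe sets, a trended or robust prior, array weights, the replicate number as a block, a 2-fold minimum, a fit of only the 2 groups compared, and leaving out each array. A comparison of 20% with 1% oxygen, and a fit without 2 arrays that lay apart, were added after seeing the data.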

Results

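The data are transcript levels of EC1118, a commercial wine yeast, grown at steady state in nitrogen-limited chemostats on a synthetic grape must at pH 3.5 and a dilution rate of 0.1 per hour. The 4 groups of 3 arrays differ in the oxygen of the sparging gas, and the labels tie these levels to oxygen met during wine making. Arrays correlated with the mean of the other arrays of their group at 0.94 to 0.992. The lowest value belonged to 1% oxygen array 3, whose deviations from its group mean had an SD of 0.548, against 0.189 to 0.399 for the other 11 arrays. Anaerobic array 1 also differed from its partners, with a median 1.23 higher over the general stress list and 1.37 higher over the iron uptake list.

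**Figure D1:**
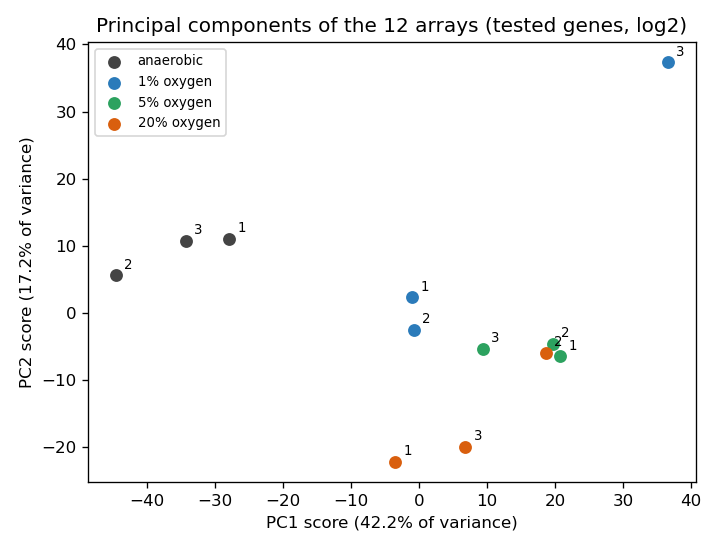
Scores of the 12 arrays on the first (x, 42.2% of variance) and second (y, 17.2%) principal components of the tested genes, coloured by group and numbered by replicate. The anaerobic arrays lie at the left, between -44.6 and -27.9 on the x axis, and 1% oxygen array 3 lies apart at 36.6 and 37.3.

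The comparison of 20% oxygen with anaerobic cultures asks which genes differ between the lowest and highest oxygen among the groups analysed here. Most of the sterol uptake and mannoprotein genes known from anaerobic growth fell. HPF1, a mannoprotein that limits protein haze in wine, fell from 10.7 ± 0.56 to 4.73 ± 1.35 (-5.96 ± 0.63). The cell wall mannoproteins TIR4 (-5.73 ± 0.91), DAN1 (-5.39 ± 0.90) and TIR2 (-4.84 ± 0.44) fell, as did HEM13 (-4.63 ± 0.41), which encodes an oxygen-requiring enzyme of heme synthesis. The largest rise was in PUT4, a proline permease gene, from 5.86 ± 1.08 to 10.7 ± 0.44 (4.89 ± 0.63). The allantoate permease gene DAL5 rose (3.59 ± 0.61), and so did MLS1 (3.06 ± 0.44), the malate synthase of the glyoxylate cycle.

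The other large falls at 20% oxygen were HUG1 (-5.33 ± 0.43), an inhibitor of ribonucleotide reductase, HES1 (-5.24 ± 0.58), of the oxysterol-binding family, SET4 (-4.81 ± 0.61), the alcohol dehydrogenase gene ADH7 (-4.80 ± 0.40) and the peroxidase gene TSA2 (-4.25 ± 0.39). The other large rises were the sulfate permease gene SUL1 (4.66 ± 1.19), VBA3 (4.14 ± 0.98), the alpha-factor gene MF(ALPHA)1 (3.95 ± 0.46), the heme oxygenase gene HMX1 (3.93 ± 0.86), SEO1 (3.41 ± 0.75), the ferric reductase gene FRE2 (3.38 ± 0.87) and the phosphate transporter gene PHO84 (3.23 ± 0.59). Among these 20 genes the adjusted p lay between 9.92e-05 for HUG1 and 0.0344 for FRE2. Of the 20, 15 kept their call with each array left out in turn, and SUL1, VBA3, HMX1, SEO1 and FRE2 did not, with adjusted p up to 0.108. With the replicate number as a block FRE2 was not called (adjusted p = 0.0528). SUL1 had an SD of 3.33 over the 20% arrays.

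Among the sterol uptake and mannoprotein genes, 10 of 11 fell at 20% oxygen (11 adjusted over the list alone, median -3.32), including the sterol importer gene AUS1 (-3.32 ± 0.35), TIR1 (-4.14 ± 0.62) and the regulator gene UPC2 (-2.64 ± 0.33). The list was called (adjusted p = 8.29e-14, and adjusted p = 0.15 with an estimated correlation). Of the 12 hypoxic genes, 4 fell (8 adjusted over the list alone, median -0.89), among them ANB1 (-2.14 ± 0.22), a hypoxic form of a translation factor, and AAC3 (-2.02 ± 0.32), a hypoxic ADP/ATP carrier. This list was called (adjusted p = 4.49e-07, and adjusted p = 0.0332 with an estimated correlation), and no other list kept its call with an estimated correlation. The aerobic partner of AAC3, PET9, rose (1.08 ± 0.26), and HYP2, the partner of ANB1, differed by 0.09 ± 0.16 (adjusted p = 0.785). Of 14 oxygen and heme regulators, 4 fell (5 adjusted over the list alone, median -0.65, adjusted p = 0.00418, and adjusted p = 0.458 with an estimated correlation), among them IXR1 (-1.73 ± 0.35). Of 8 heme synthesis genes, HEM13 and HEM14 (-1.08 ± 0.21) fell (2 adjusted over the list alone, adjusted p = 0.0131, and adjusted p = 0.178 with an estimated correlation), and the list was not called without 20% oxygen array 3 (adjusted p = 0.0512). The calls of PET9 (without anaerobic array 2 or 3 or 20% oxygen array 1 or 2, adjusted p up to 0.121), IXR1 (without anaerobic array 2 or 20% oxygen array 2, up to 0.0533) and HEM14 (without anaerobic array 2, 0.0551) ended on leaving out an array. All 12 called PAU genes, of 13 tested, were lower (median -2.78).

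Respiratory chain lists differed in their calls at 20% oxygen. Of 18 genes of complexes III and IV and cytochrome c, 6 rose (13 adjusted over the list alone, median 0.97), among them COX5A (1.84 ± 0.33), an aerobic isoform of cytochrome c oxidase, and COX4 (1.63 ± 0.34). The list was called (adjusted p = 3.87e-07, and adjusted p = 0.458 with an estimated correlation). The hypoxic isoform COX5B (-0.37 ± 0.24, adjusted p = 0.395) and CYC1 (2.21 ± 0.81, adjusted p = 0.113) were not called. The 8 genes of complex II and the NADH dehydrogenases had 0 called members (3 higher adjusted over the list alone), and camera did not call that list (adjusted p = 0.232). Of 15 ATP synthase genes, 3 rose (7 adjusted over the list alone, median 0.56), among them INH1 (1.34 ± 0.30) and ATP7 (0.87 ± 0.23), with an adjusted p = 7.95e-05 for the list and adjusted p = 0.458 with an estimated correlation. The calls of COX4 (adjusted p up to 0.0655) and INH1 (up to 0.0933) ended without anaerobic array 2 or 3 or 20% oxygen array 2. That of ATP7 ended without any of the anaerobic arrays or 20% oxygen array 1 or 2 (up to 0.148), and with the replicate number as a block (0.0749). Of 22 iron uptake genes, 6 rose (13 adjusted over the list alone, median 1.27, adjusted p = 1.11e-08, and adjusted p = 0.458 with an estimated correlation), and the median was 0.66 without anaerobic array 2. The iron uptake and respiratory chain lists were also higher in anaerobic array 1 than in the other anaerobic arrays, by medians of 1.37 and 0.97.

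**Figure D2:**
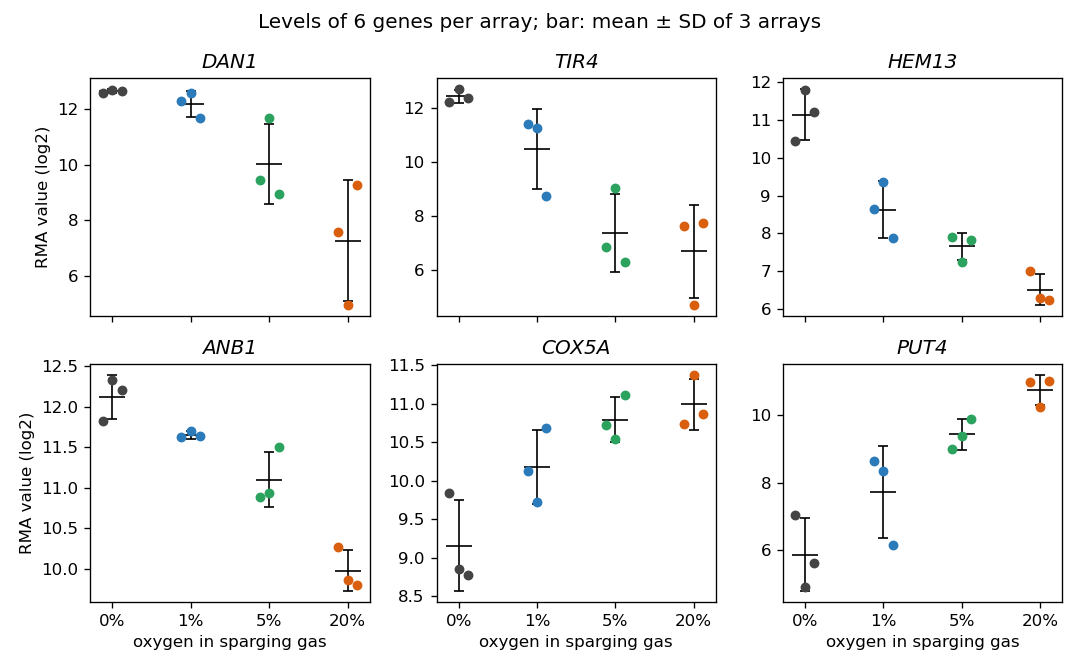
RMA log2 level (y) of 6 genes against oxygen in the sparging gas (x), a point per array with the mean ± SD of 3 arrays. DAN1, TIR4, HEM13 and ANB1 have lower means and COX5A and PUT4 higher means at 20% oxygen than in anaerobic cultures.

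At 20% oxygen, 5 further lists were called, each with at most 2 called genes and each lost on leaving out an array. Of 25 ergosterol synthesis genes, ERG6 (-2.39 ± 0.51) and CYB5 (-1.27 ± 0.30) fell (2 adjusted over the list alone, median -0.28, adjusted p = 0.00213, and adjusted p = 0.653 with an estimated correlation), and without anaerobic array 1 the list had an adjusted p = 0.0639. Of 22 sulfate and methionine genes, SUL1 rose (2 adjusted over the list alone, median 0.72, adjusted p = 0.00213, and adjusted p = 0.653 with an estimated correlation), with a median of 0.30 and an adjusted p = 0.142 without 20% oxygen array 3, and a median of 1.21 without 20% oxygen array 2. Of 19 general stress and storage carbohydrate genes, HSP42 (-2.03 ± 0.51) and GDB1 (-1.03 ± 0.24) fell (3 adjusted over the list alone, median -0.36, adjusted p = 0.0183, and adjusted p = 0.664 with an estimated correlation). Without anaerobic array 1, in which this list was higher by 1.23, the median was -0.03 and the adjusted p = 0.521, and without 20% oxygen array 1 the adjusted p = 0.0615. The median was -0.70 without anaerobic array 2 and -0.59 without 20% oxygen array 3. The 16 tricarboxylic acid cycle genes had no called member (0 adjusted over the list alone, median 0.35, adjusted p = 0.0322, and adjusted p = 0.653 with an estimated correlation), and the list was lost without anaerobic array 2 (adjusted p = 0.0568), anaerobic array 3 (adjusted p = 0.0867) or 20% oxygen array 3 (adjusted p = 0.0971). Of 16 haploid mating genes, which mark another cell type and of which 14 were dim, MF(ALPHA)1 and STE2 (1.03 ± 0.24) rose (2 adjusted over the list alone, adjusted p = 0.0322, and adjusted p = 0.653 with an estimated correlation), and the list was lost without anaerobic array 1 (adjusted p = 0.0787) or 20% oxygen array 3 (adjusted p = 0.0971). The gene calls of ERG6 (without anaerobic array 2 or 20% oxygen array 2 or 3, adjusted p up to 0.0665), CYB5 (without anaerobic array 1 or 2 or 20% oxygen array 2 or 3, up to 0.105) and HSP42 (without anaerobic array 1 or 3 or 20% oxygen array 1 or 2, up to 0.129) also ended on leaving out an array. So did those of GDB1 (without anaerobic array 1 or 3 or 20% oxygen array 2, up to 0.09) and STE2 (without any of the anaerobic arrays or 20% oxygen array 1 or 2, up to 0.0772).

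In all, 431 of 5449 genes were called at 20% oxygen, 178 higher and 253 lower, and 302 of them differed at least 2-fold. The count was 153, 156 and 181 without anaerobic array 2, anaerobic array 3 and 20% oxygen array 2, and 758 without 1% oxygen array 3, which shares the estimate of the spread. It was 1504 with array weights, whose estimation did not converge.

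At 5% oxygen most of the sterol uptake and mannoprotein genes fell, as at 20%. HPF1 had the largest fall among the named genes, from 10.7 ± 0.56 to 5.28 ± 1.02 (-5.41 ± 0.63), and TIR4 (-5.04 ± 0.91), ADH7 (-4.32 ± 0.40), HUG1 (-4.24 ± 0.43), HES1 (-4.06 ± 0.58), PBI1 (-3.70 ± 0.47), TIR2 (-3.67 ± 0.44), HEM13 (-3.49 ± 0.41), SET4 (-3.40 ± 0.61) and DAN4 (-3.37 ± 0.66) fell. The largest rises were VBA3 (3.84 ± 0.98), FRE2 (3.57 ± 0.87), PUT4 (3.57 ± 0.63), HMX1 (3.29 ± 0.86), DAL5 (3.17 ± 0.61), YTP1 (2.98 ± 0.58), the siderophore transporter gene ENB1 (2.73 ± 0.79), MLS1 (2.60 ± 0.44), SEO1 (2.50 ± 0.75) and NFT1 (2.47 ± 0.62). Of these 20 genes, 14 kept their call with each array left out, and VBA3, FRE2, HMX1, ENB1, SEO1 and NFT1 did not, with adjusted p up to 0.136. DAN1 was not called at 5% oxygen (-2.62 ± 0.90, adjusted p = 0.0662).

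Among the lists at 5% oxygen, 10 of 11 sterol uptake and mannoprotein genes fell (11 adjusted over the list alone, median -2.53, adjusted p = 1.41e-08, and adjusted p = 0.446 with an estimated correlation). Of 12 hypoxic genes, 6 fell (7 adjusted over the list alone, median -0.81, adjusted p = 0.00068, and adjusted p = 0.246 with an estimated correlation), and of 14 regulators, 6 fell (8 adjusted over the list alone, median -1.15, adjusted p = 0.00068, and adjusted p = 0.469 with an estimated correlation), among them CYC8 (-2.26 ± 0.32). Of 18 respiratory chain genes, 5 rose (10 adjusted over the list alone, median 0.81, adjusted p = 0.000387, and adjusted p = 0.805 with an estimated correlation). Of 15 ATP synthase genes, 4 rose (8 adjusted over the list alone, median 0.63, adjusted p = 0.000943, and adjusted p = 0.756 with an estimated correlation). Of 22 iron uptake genes, 9 rose (14 adjusted over the list alone, median 1.38, adjusted p = 9.56e-08, and adjusted p = 0.756 with an estimated correlation), with a median of 0.82 without anaerobic array 2. Of 66 mitochondrial ribosomal protein genes, 2 rose and 1 fell (0 adjusted over the list alone, median 0.57, adjusted p = 4.82e-05, and adjusted p = 0.924 with an estimated correlation). The median level of that list was 8.27 in 5% oxygen array 2, near the 8.19 to 8.22 of the anaerobic arrays, and 9.05 and 9.03 in 5% oxygen arrays 1 and 3. Of 14 ester and fusel alcohol genes, ADH7 and the acetyltransferase gene ATF1 (-1.52 ± 0.26) fell (2 adjusted over the list alone, median -0.56, adjusted p = 0.0415, and adjusted p = 0.469 with an estimated correlation). That list was lost without anaerobic array 2 (adjusted p = 0.051), 5% oxygen array 1 (adjusted p = 0.0512) or 5% oxygen array 2 (adjusted p = 0.0534).

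In all, 889 genes were called at 5% oxygen, 290 higher and 599 lower, and all 13 PAU genes were lower. With quantile scaling the split was 456 higher and 563 lower. After a trend on gene length was removed from each array, a step added after seeing the data, it was 505 higher and 515 lower. The count was 400, 483, 457 and 410 without anaerobic array 2, anaerobic array 3, 5% oxygen array 1 and 5% oxygen array 2, and 1303 without 1% oxygen array 3 (585 differed at least 2-fold). It was 1602 when only the 2 groups were fitted and 2442 with array weights, whose estimation did not converge.

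The comparison of 1% oxygen with anaerobic cultures asks what the lowest oxygen level analysed here changed. HPF1 fell from 10.7 ± 0.56 to 7.27 ± 0.48 (-3.42 ± 0.63) and HEM13 fell from 11.1 ± 0.67 to 8.62 ± 0.75 (-2.52 ± 0.41). The other large falls were YSR3 (-2.95 ± 0.64), the ribosome assembly gene REI1 (-2.63 ± 0.61), the ribonucleotide reductase gene RNR3 (-2.43 ± 0.41), PXR1 (-2.42 ± 0.31), ZDS1 (-2.29 ± 0.61), SPT2 (-2.28 ± 0.31), MTH1 (-2.25 ± 0.56) and DAN4 (-2.25 ± 0.66). The largest rises were the ferric reductase genes FRE2 (3.30 ± 0.87) and FRE3 (1.73 ± 0.44), YTP1 (2.11 ± 0.58), the cysteine transporter gene YCT1 (1.96 ± 0.56), TMT1 (1.65 ± 0.28), PHR1 (1.60 ± 0.36), RTC2 (1.56 ± 0.26), ERS1 (1.52 ± 0.28), AVT2 (1.51 ± 0.18) and COS7 (1.37 ± 0.33). Of these 20 genes only AVT2, HPF1, HEM13, RNR3, PXR1 and SPT2 kept their call with each array left out. The other 14 had adjusted p up to 0.147, and the difference of FRE2 ranged from 2.05 to 4.4. With the replicate number as a block YTP1 (adjusted p = 0.0516) and ZDS1 (adjusted p = 0.051) were not called. DAN1 differed by -0.46 ± 0.90 (adjusted p = 0.745).

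Among the lists at 1% oxygen, 3 of 11 sterol uptake and mannoprotein genes fell (5 adjusted over the list alone, median -1.07, adjusted p = 0.00252, and adjusted p = 0.823 with an estimated correlation). Of 14 regulators, 4 fell (6 adjusted over the list alone, median -0.76, adjusted p = 0.00388, and adjusted p = 0.823 with an estimated correlation). Of 22 iron uptake genes, 5 rose (13 adjusted over the list alone, median 1.16, and 0.60 without anaerobic array 2, adjusted p = 5.09e-06, and adjusted p = 0.823 with an estimated correlation). Of 15 ATP synthase genes, 5 rose (7 higher and 1 lower adjusted over the list alone, median 0.50, adjusted p = 0.00117, and adjusted p = 0.823 with an estimated correlation), with medians of 0.24 and 0.77 without 1% oxygen arrays 3 and 2. Of 64 ribosome biogenesis genes, 15 fell (23 lower and 1 higher adjusted over the list alone, median -0.58, adjusted p = 8.78e-06, and adjusted p = 0.978 with an estimated correlation), among them NOP8 (-2.27 ± 0.38) and UTP14 (-1.93 ± 0.28). NOP8 was not called without anaerobic array 2 (adjusted p = 0.0503). The median was -0.36 without 1% oxygen array 3, in which these genes had a median difference of -0.72 from the other 1% arrays. The 66 mitochondrial ribosomal protein genes had no called member (0 adjusted over the list alone, median 0.51, and 0.30 without 1% oxygen array 3; adjusted p = 0.00112, and adjusted p = 0.978 with an estimated correlation). Of 18 respiratory chain genes, COX4 (1.29 ± 0.34) and COX9 (0.78 ± 0.20) rose (2 adjusted over the list alone, adjusted p = 0.0329, and adjusted p = 0.978 with an estimated correlation). That list was lost with quantile scaling (adjusted p = 0.0968), and without anaerobic array 2 (adjusted p = 0.159), anaerobic array 3 (adjusted p = 0.218) or 1% oxygen array 3 (adjusted p = 0.101). The call of COX4 ended without the same arrays (adjusted p up to 0.121). That of COX9 ended without any of the anaerobic arrays or 1% oxygen array 1 or 3 (up to 0.0853), and with the replicate number as a block (0.0528). Of 12 hypoxic genes, 3 fell (6 lower and 1 higher adjusted over the list alone, median -0.51), and camera did not call the list (adjusted p = 0.0668) while fry did (adjusted p = 0.0176). Of 8 heme synthesis genes, 3 fell (3 adjusted over the list alone, median -0.28), and camera did not call that list (adjusted p = 0.391) while fry did (adjusted p = 0.0464).

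In all, 895 genes were called at 1% oxygen, 287 higher and 608 lower, and all 13 PAU genes were lower. With quantile scaling the split was 475 higher and 486 lower, and with median scaling 392 and 517. The count fell to 36 without anaerobic array 2, 172 without anaerobic array 3, 443 without anaerobic array 1 and 322 without 1% oxygen array 3, so it rests on single arrays (513 differed at least 2-fold). It was 523 with the replicate number as a block, 447 when only the 2 groups were fitted and 1712 with array weights, whose estimation did not converge.

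**Figure D3:**
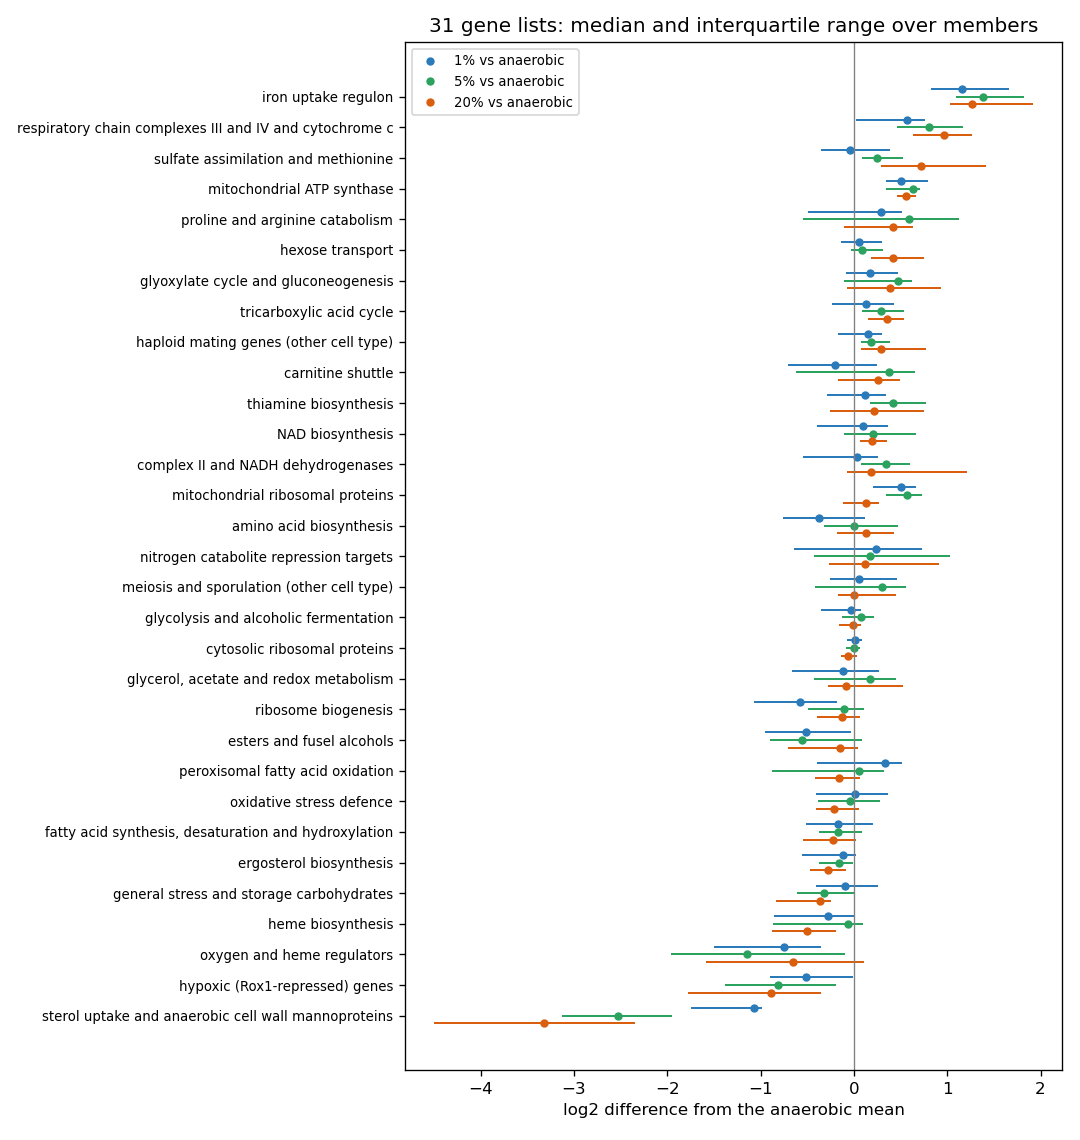
Median (point) and interquartile range (line) over members of the log2 difference from the anaerobic mean (x) for each of 31 gene lists (y), by oxygen level. The sterol uptake and mannoprotein list has medians of -1.07, -2.53 and -3.32 at 1%, 5% and 20% oxygen.

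The 3 comparisons share the anaerobic arrays. Of the called genes, 141 were higher and 458 lower at both 1% and 5% oxygen, 143 higher and 242 lower at both 5% and 20%, and 81 higher and 207 lower at both 1% and 20%, with 0 in opposite directions. Independent lists of these sizes would share 15.3 and 66.8, 9.47 and 27.8, and 9.38 and 28.2 genes. In 100 simulations without effects the highest overlap was 1 gene. Hardly any gene is called without effects, so that number does not measure what the shared arrays add. The covariance of the differences was 0.45, 0.463 and 0.349, against simulated values of 0.0493, 0.0492 and 0.0495. The controls were too few to be split, so part of the overlap, and of its common direction, may come from the shared arrays.

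No gene was called by limma between successive oxygen levels. Array weights gave 2 genes between 5% and 1% oxygen, and leaving out 5% oxygen array 2 gave 6. Between 5% and 1% oxygen, 265 genes had an unadjusted p under 0.05, and the smallest adjusted p was 0.12, for TIR2 (-2.64 ± 0.44), followed by 0.186 for AUS1 (-1.82 ± 0.35) and ADH7 (-2.14 ± 0.40). Between 20% and 5% oxygen, 149 genes had an unadjusted p under 0.05, and the smallest adjusted p was 0.503. ANB1 differed by -1.12 ± 0.22 (adjusted p = 0.713), DAN1 by -2.77 ± 0.90 (adjusted p = 0.999) and HEM13 by -1.14 ± 0.41 (adjusted p = 0.999).

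Between successive levels no list had a called member, and the list calls rest on the preset correlation. The sterol uptake and mannoprotein list was lower at 5% than at 1% oxygen (median -1.13, 4 lower adjusted over the list alone and 0 over all genes, adjusted p = 4.14e-11, and adjusted p = 0.254 with an estimated correlation). Camera called 7 lists between 5% and 1% oxygen and 5 between 20% and 5% oxygen, fry called 0 in either, and the smallest adjusted p with an estimated correlation were 0.254 and 0.156. Without 1% oxygen array 3, 3 of the lists called between 5% and 1% oxygen were lost. These were ribosome biogenesis (median 0.40, adjusted p = 7.98e-09, and adjusted p = 0.129 without it), amino acid biosynthesis (median 0.36, adjusted p = 1.38e-06, and adjusted p = 0.254 without it) and peroxisomal fatty acid oxidation (median -0.25, adjusted p = 0.00566, and adjusted p = 0.995 without it, with the direction turned). The ribosome biogenesis median was 0.16 without that array and 0.26 without 5% oxygen array 3, and the amino acid median was 0.14 without 1% oxygen array 3. The peroxisomal median was 0.05 without 1% oxygen array 3, -0.49 without 1% oxygen array 2, and -0.15 and -0.13 without 5% oxygen arrays 2 and 3. With an estimated correlation each of these had an adjusted p = 0.821. The hypoxic list (median -0.34, adjusted p = 0.00284, and adjusted p = 0.254 with an estimated correlation) was lost without 1% oxygen array 2 (adjusted p = 0.0884). The respiratory chain list (median 0.31, adjusted p = 0.0108, and adjusted p = 0.821 with an estimated correlation) was lost without 1% oxygen array 1 (adjusted p = 0.0984) or 2 (adjusted p = 0.377), or 5% oxygen array 1 (adjusted p = 0.0527) or 3 (adjusted p = 0.156). Its median was 0.02 and 0.51 without 1% oxygen arrays 2 and 3 and 0.17 without 5% oxygen array 3. The tricarboxylic acid cycle list (median 0.28, adjusted p = 0.0221, and adjusted p = 0.821 with an estimated correlation) was lost without 1% oxygen array 1 (adjusted p = 0.273) or 5% oxygen array 1 (adjusted p = 0.569).

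The mitochondrial ribosomal protein list was lower at 20% than at 5% oxygen, with a median difference of -0.44. The arrays overlapped, with list median levels of 9.05, 8.27 and 9.03 at 5% oxygen and 8.19, 8.98 and 7.78 at 20%. The median difference was -0.21 without 20% oxygen array 3, -0.73 without 20% oxygen array 2 and -0.70 without 5% oxygen array 2. Deviations from the group mean followed gene length most in 20% oxygen array 3 (Spearman's rho = 0.481 across genes, which are not independent). The list's adjusted p = 1.15e-18, and adjusted p = 0.972 with an estimated correlation. The other lists called in this step were each lost on leaving out an array. The sterol uptake and mannoprotein list (median -0.61, adjusted p = 0.00122, and adjusted p = 0.972 with an estimated correlation) was lost without 5% oxygen array 2 (adjusted p = 0.158) or 20% oxygen array 2 (adjusted p = 0.334), with medians of -0.04 and -0.27, and had a median of -0.95 without 5% oxygen array 3. The hypoxic list (median -0.30, adjusted p = 0.00206, and adjusted p = 0.156 with an estimated correlation) was lost without 5% oxygen array 3 (adjusted p = 0.0682) or 20% oxygen array 2 (adjusted p = 0.261). Its median was -0.18, -0.15 and -0.46 without 5% oxygen array 2 and 20% oxygen arrays 1 and 3. The heme synthesis list (median -0.25, adjusted p = 0.00569, and adjusted p = 0.156 with an estimated correlation) was lost without the same arrays (adjusted p = 0.0836 and 0.0789), with a median of -0.42 without 20% oxygen array 2. The sulfate and methionine list (median 0.58, adjusted p = 2.81e-05, and adjusted p = 0.972 with an estimated correlation) was lost without 5% oxygen array 3 (adjusted p = 0.0697) or 20% oxygen array 3 (adjusted p = 0.594), with medians of 0.37 and 0.03, and had a median of 1.18 without 20% oxygen array 2.

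Fry called 4, 8 and 9 lists at 1%, 5% and 20% oxygen against anaerobic cultures, of which camera also called 1, 6 and 7. The lists called by fry alone were heme synthesis (adjusted p = 0.0464), hypoxic genes (adjusted p = 0.0176) and esters and fusel alcohols (adjusted p = 0.0356) at 1% oxygen. At 5% oxygen they were heme synthesis and NAD synthesis (adjusted p = 0.0481 for each), and at 20% oxygen esters and fusel alcohols (adjusted p = 0.0451) and NAD synthesis (adjusted p = 0.0163). Across genes, which are not independent, the change against anaerobic cultures followed gene length with a Spearman's rho of -0.28, -0.19 and -0.05 at 1%, 5% and 20% oxygen, and the list tests do not adjust for length.

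Of the 31 lists, 16 were not called by camera at any oxygen level against anaerobic cultures. Among 128 cytosolic ribosomal protein genes, 3, 1 and 0 fell at 1%, 5% and 20% oxygen (0 adjusted over the list alone), with adjusted p of 0.969, 0.797 and 0.175 for the list. Among 19 genes of glycolysis and alcoholic fermentation, 1, 1 and 0 fell (0 adjusted over the list alone), with adjusted p of 0.795, 0.846 and 0.714. Among 26 targets of nitrogen catabolite repression, 2 rose and 1 fell at 20% oxygen (4 and 1 adjusted over the list alone, adjusted p = 0.22). At 5% oxygen 4 of them rose and 2 fell (5 and 2 adjusted over the list alone, adjusted p = 0.412). Among 31 oxidative stress genes, 2 fell at 20% oxygen (2 adjusted over the list alone, adjusted p = 0.0861). At 20% oxygen the adjusted p was 0.0837 for the glyoxylate cycle, 0.336 for peroxisomal fatty acid oxidation and 0.914 for the carnitine shuttle. It was 0.169 for hexose transport, 0.83 for glycerol and acetate metabolism, 0.192 for proline and arginine catabolism and 0.0837 for NAD synthesis. At 5% oxygen, 3 of the 8 proline and arginine catabolism genes rose and 2 fell (4 and 2 adjusted over the list alone, adjusted p = 0.412 for the list). The values that follow are again for 20% oxygen. It was 0.132 for fatty acid synthesis, 0.675 for thiamine synthesis, 0.31 for amino acid synthesis and 0.675 for meiosis genes, of which 14 of 16 were dim.

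The moderated F test for any difference between the 4 levels called 553 genes, with a smallest adjusted p of 0.000354. Its count was 207, 100, 102, 356 and 280 without anaerobic arrays 1, 2 and 3 and 5% oxygen arrays 1 and 2. It was 308 with the replicate number as a block and 2333 with array weights. Of the other fixed genes, ROX1, a repressor of hypoxic genes, was not called at any oxygen level (-2.23 ± 0.92 at 1%, -2.13 ± 0.92 at 5% and -1.84 ± 0.92 at 20%), and OLE1, the fatty acid desaturase gene, differed by -0.69 ± 0.23 at 20% oxygen (adjusted p = 0.0902). At 20% oxygen CTT1 (-0.72 ± 0.92), SOD2 (0.13 ± 0.35), HAP4 (-0.05 ± 0.42), CIT1 (1.02 ± 0.34), ICL1 (-0.34 ± 0.34), FOX2 (0.36 ± 0.31), PUT1 (0.42 ± 0.32), GAP1 (1.04 ± 0.32), HAP1 (-0.69 ± 0.20), HEM1 (-0.71 ± 0.34), HMG1 (0.28 ± 0.51), HMG2 (-0.52 ± 0.21) and CYC7 (-0.34 ± 0.68) were not called.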

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

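A signal appeared in probe sets outside the comparisons, the 218 that have no gene name here. When all probe sets were tested, 31 of them were called at 1% oxygen against anaerobic (14.2%), 27 at 5% oxygen (12.4%) and 16 at 20% oxygen (7.34%). Among the named genes the shares were 16.4%, 16.3% and 7.91%.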

How the results depend on the processing

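The 2-array fit was chosen after seeing the data. The counts against anaerobic and of the F test rest on single arrays. Leaving out 1 array at a time gave 36 to 985 genes at 1% oxygen, 400 to 1303 at 5%, 153 to 758 at 20%, 0 to 6 for 5% against 1%, 0 to 0 for 20% against 5% and 100 to 744 for the F test. Without both 1% oxygen array 3 and anaerobic array 1, 155 genes were called at 1% oxygen. With array weights, whose estimation warned of not converging, 1712, 2442 and 1504 genes were called at 1%, 5% and 20% oxygen, 2 for 5% against 1% and 2333 by the F test. Fitting only the groups compared gave 447 genes at 1% and 1602 at 5% oxygen, and a 2-fold minimum left 513 and 585. Apart from fewer arrays or a stricter rule, the cause was not tested.

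Replicate numbers did not pair the arrays: in their deviations from the group means, 2 of 18 same-numbered pairs correlated above 0.1. With the replicate number as a block, 523 genes were called at 1% oxygen and 308 by the F test, and no other count with the block moved by over 1.5 times. Quantile and median scaling, leaving out dim genes, the mean of probe sets, all probe sets and a trended or robust prior kept each gene count within 1.5 times. Of 39 called lists, the block changed no call, quantile scaling ended 2, leaving out dim genes 5, the 2-array fit 6, leaving out 1 array 18 (1 of them with its direction reversed), fry 25 and an estimated correlation 38. The peroxisomal list was lower at 5% than at 1% oxygen and turned direction without 1% oxygen array 3 (adjusted p = 0.995, within 0.00245 to 0.995 over the alternatives tried for it). This check covered 94 named genes, a part of those the naming rule gives. Leaving out 1 array ended 32 of their calls and the block 5. Calls of other genes named by the rule ended too, so these counts are a lower bound. The values carry no background measurement, so signal over background is not given for the dim genes.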

Other observations

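The tests of the patterns in this part were chosen after their results were seen. Those on other splits of the arrays were planned. In a comparison added after the successive steps gave no call, 20 genes differed between 20% and 1% oxygen. The 5 higher genes were PHO84 (3.78 ± 0.59), FLO1 (3.10 ± 0.41), MF(ALPHA)1 (adjusted p = 0.0146), FLO9 (2.25 ± 0.38) and RKM5 (0.98 ± 0.18), and FLO1 and FLO9 are similar flocculin genes whose probes may not tell them apart. The 15 lower genes included DAN1 (-4.94 ± 0.90), HES1 (-4.22 ± 0.58), SET4 (-3.74 ± 0.61), HUG1 (-3.09 ± 0.43), and the membrane protein genes IZH4 (-2.69 ± 0.46) and IZH2 (-1.46 ± 0.21). With quantile scaling 19 genes were called, and leaving out each array was not tried for this comparison's genes. Camera called 13 lists, and 0 with an estimated correlation, and fry called 3.

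1% oxygen array 3 lies apart from the other 2 arrays of its group. Gene length explained 6.68% of the rank variance of its deviation (Spearman's rho = -0.259), less than the 23.2% in 20% oxygen array 3, where the trend had the opposite sign (0.481). Anaerobic array 3 (-0.315) and 20% oxygen array 2 (-0.312) had stronger trends of the same sign and did not lie apart. A length trend thus does not set this array apart, but partly degraded RNA is not excluded. Its closest other group was 5% oxygen, at a mean correlation of 0.949 against 0.937 with its own group. The lowest correlation within the 5% group was 0.974, and 1% oxygen arrays 1 and 2 correlated at 0.985. The array fell short of both, so correlation cannot decide its label. A second test left the label open too: the gap between its positions by genes that fell and rose was 41.1% of the distance from anaerobic to 20% oxygen, and 1% oxygen array 2 had 40%. This array's positions were 133% by genes that fell and 91.4% by genes that rose. The 5% arrays had 102% to 129% and 83.3% to 97.3%, and the other 1% arrays 73.5% to 90.8% and 50.8% to 70.2%. Its sterol uptake and mannoprotein list (-1.77 from anaerobic arrays 2 and 3) lay between the other 1% arrays (-0.998 and -1.06) and the 5% arrays (-1.93 to -3.69). A wrong label thus stays open. Parts of the profile of 1% oxygen array 3 lay outside every group, which a swapped label would not by itself give. On the second principal component it scored 37.3, against -6.46 to -4.57 for the 5% arrays and at most 11.0 for any other array. Its peroxisomal list had a median level of 6.46, against at most 6.18 in any other array. No biological explanation was tested.

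Anaerobic array 1 had higher general stress, iron uptake and respiratory chain genes than the other anaerobic arrays, with 19 of 19, 22 of 22 and 17 of 18 members higher, and all 11 sterol uptake and mannoprotein genes lower. The median difference of these 11 genes was -0.30, or 8.35% of the way to the 20% oxygen arrays. The nearest 1% or 5% array had -0.998. The list's median level was 9.52, against 10.66 and 10.36 in the other anaerobic arrays and 9.30, 9.23 and 8.76 in the 1% arrays. By that measure, which does not compare each gene with itself, the array lay nearer to 1% oxygen arrays 1 and 2 than to its own group. The highest levels at 5% and 20% oxygen were 8.14 and 7.09. Both measures argue against a 5% or 20% label, but only the first against a 1% label. On the first principal component the array scored -27.9, against -44.6 and -34.3 for the other anaerobic arrays. The 1% arrays scored -1.01, -0.724 and 36.6. The mean correlation of anaerobic array 1 was 0.974 with the other anaerobic arrays, which correlated at 0.988. Its highest with another group was 0.96, with 1% oxygen arrays 1 and 2, which correlated at 0.985. Leaving out 1% oxygen array 3, which lies apart, was decided after the result was seen. With that array included the value was 0.941 against a lowest of 0.928, which gave no decision. Anaerobic array 1 correlated best with its own group but fell short of the correlation within it, so this test does not decide its label. Whether oxygen may have reached this culture before freezing was not told apart from a stress response. The stress list exceeded the respiratory list by 0.257, against an SD of 0.981 over the members of the stress list. That SD is the spread of single genes and not the error of a difference between list medians, so this comparison cannot decide. No biological explanation was tested within the anaerobic group.

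Falls outnumber rises among genes called at 1% oxygen, with 67.9% of calls lower. With quantile scaling 50.6% were lower, so the excess of falls over all calls may come from the scaling of the arrays. Of the 513 called genes that differed at least 2-fold, 63 were higher and 450 lower. That split was not examined with quantile scaling, so the scaling result does not cover these larger differences. After a trend on gene length was removed from each array, 57.6% of all calls were lower, which leaves open whether gene length adds to the excess. At 5% oxygen, with 290 genes higher and 599 lower, the same removal gave 505 higher and 515 lower. At 20% oxygen, with 178 higher and 253 lower, it gave 306 higher and 262 lower. The split of calls by direction thus depended on gene length at these levels too. A global fall of transcripts at 1% oxygen stays open as well, since scaling would remove it.

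The 6 arrays of a comparison have 10 splits, the real one included, too few for a share under 0.05. At 1%, 5% and 20% oxygen against anaerobic, 1 split, the real one, gave as many genes, with 895, 889 and 431 genes against 2, 0 and 0 in the highest other split. For 5% against 1% and 20% against 5% oxygen the real count was 0, which every split reaches, so this comparison of counts tests nothing there. The highest other split gave 6 and 1 genes. For the F test, 1 of 100 splits of the 12 arrays, the real one, gave as many as 553 genes. The highest other split gave 389. If the arrays are independent cultures, this argues against chance there at that number of splits. The labels do not say whether the arrays of a group came from separate chemostats. If they did not, these splits cannot exclude chance differences between cultures.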
